A study of Mus musculus with 12 samples.

How the data were processed

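RNA was sequenced from 12 mouse samples in 4 groups of 3 libraries: naive cortex, and tumours of the fusions YAP1-TFE3, YAP1-FAM118B and YAP1-MAMLD1-dR3R1. The deposited values are raw counts of reads per gene symbol, made by the authors with HTSeq on genome build mm10, per the submitters' processing notes. Tool versions, the aligner, the gene annotation, the strand setting and filters are not given in the sources used here, so reads of a gene and of an overlapping or antisense neighbour, or of near-identical copies, cannot be told apart. Of 24421 symbols, 24300 matched the RefSeq table of assembly GRCm38.p6, which gave the coordinates, and 4096 had no count in any library. Total counts were between 19850220 and 24760814 per library, and the ribosomal repeat gene Rn45s took 0.340 to 0.831% of them.

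The tests used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 16364, and libraries were scaled with TMM factors. A quasi-likelihood negative binomial model was fitted to all libraries, so that the groups shared an estimate of the spread, and 6 contrasts were tested with Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM, the count of a gene scaled to the library size, is given as mean and SD over the replicates of a group, and log2 CPM used a prior count of 2. A gene was shared when it passed in the same direction in every fusion against naive, and set apart in a fusion when it passed in the same direction against both other fusions. Overlaps were set beside the number expected of independent lists and beside 20 simulations in which every group, naive included, was drawn from the naive means.

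The 26 gene lists were written from general knowledge of the field: YAP/TEAD targets, Hippo components, lysosome and TFE targets, cell cycle, motile cilia, neural stem cells, neurons, myelin, oligodendrocyte precursors, astrocytes, microglia, monocytes and macrophages, T and NK cells, B cells, neutrophils, endothelium, pericytes, fibroblasts and meninges, extracellular matrix, interferon response, antigen presentation, hypoxia and glycolysis, AP-1 and immediate early genes, choroid plexus, blood and oxidative phosphorylation. Members called were counted over all genes tested and again with adjustment over the list alone. Camera compared each list with the other genes at a preset correlation of 0.01, adjusted over the lists within a contrast. Of the 156 combinations of list and contrast 74 passed, and none passed with the correlation estimated from the data.

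Groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took the partner genes, then genes called in every fusion against naive with all 9 tumour libraries on the same side of each naive library and a mean of at least 10 CPM, up to 10 per direction by the smallest fold change. It took up to 10 genes per direction in each fusion pair and 5 in each fusion against naive by fold change, with libraries that did not overlap and a mean of at least 5 CPM. From each list it took up to 4 members by adjusted p and up to 2 going against the majority. Predicted genes named only by number and sex-linked genes were counted but not named by this rule. A fold against a group without counts was computed against a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with a 95% counting interval.

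Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, library size only, no filter or a filter of 1 CPM in 3 libraries, a robust dispersion, a test against 2-fold (glmTreat), only the groups compared, the replicate number as a block, each library left out in turn, and tumours alone with the level of neuron and myelin genes or of microglia and macrophage genes as a covariate. Similarity was also computed over the 1000 most variable genes. A fit without both libraries that held Xist and Y-linked counts and a fit of tumours alone with no covariate were added after seeing the data. The tests were run first on libraries simulated from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. The real comparisons called far more genes, which makes the Benjamini-Hochberg cutoff less strict than in the simulation. The recovered shares therefore do not estimate how many real changes were missed. False calls in the order of the contrasts were 6 of 108, 8 of 103, 3 of 104, 4 of 105, 3 of 97 and 5 of 87, counting fusions against naive first and then YAP1-FAM118B and YAP1-TFE3 against YAP1-MAMLD1-dR3R1 and YAP1-TFE3 against YAP1-FAM118B. Splicing, fusion junctions and sequence variants need reads and were not analysed here.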

Results

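Bulk RNA sequencing measured gene expression in 12 mouse brain samples, which the labels place in 4 groups of 3 libraries each. The control group was normal cortex, called naive in the labels. The other groups were whole tumours that arose in the brain after injection of RCAS viruses, avian retroviral vectors used to deliver a gene to cells of a living mouse. Each virus carried YAP1, the transcriptional co-activator that the Hippo pathway holds back, fused to another protein. The partner was MAMLD1, a mastermind-like co-activator, FAM118B, a protein of nuclear Cajal bodies, or TFE3, a transcription factor that drives lysosomal genes. The first construct is named YAP1-MAMLD1-dR3R1, and the labels do not explain its suffix. The title of the series asks which functions the fusions have in common.

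Total counts ranged from 19850220 to 24760814 per library over 24421 genes, and the most abundant gene took at most 1.22% of them. A count of 3 corresponded to 0.121 to 0.151 CPM, the count scaled to the library size, in a single library, and such limits cover counting error only. The labels do not state that the libraries of a group came from separate animals, so p-values measure only the spread between these samples. In every group part of that spread may be technical, and in YAP1-TFE3 all of it may lie within a single animal. Correlations of log2 CPM between YAP1-TFE3 libraries, 0.911 to 0.940 over the genes tested, lay below those between naive libraries, 0.971 to 0.985. This argues against a purely technical spread in YAP1-TFE3, though pieces of a single tumour stay possible. The tissue field of the naive samples names a brain tumour although their source field names normal cortex, and the extraction protocol describes cultured cells although the design text describes frozen tumours. Naive replicate 2 held both Xist, the RNA that coats the inactive X chromosome of females, at 25.6 CPM and the Y-linked Ddx3y at 49.3 CPM. YAP1-FAM118B replicate 2 did too, with Xist at 162 CPM and Ddx3y at 29.9 CPM. Ddx3y was at least 68.9 CPM in the YAP1-TFE3 libraries, with Xist at 0.434 CPM or lower, whereas each other group held at least 1 library with Xist and no more than 0.0440 CPM of Ddx3y. Each of those groups also held a library with Ddx3y and almost no Xist. These were naive replicate 1 (62.9 and 0.0411 CPM), YAP1-MAMLD1-dR3R1 replicate 2 (75.5 and 0) and YAP1-FAM118B replicate 3 (81.6 and 0). Such values argue against a single animal behind all libraries of naive, YAP1-MAMLD1-dR3R1 or YAP1-FAM118B.

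Yap1 (chromosome 9, 7931999 to 8004638, GRCm38) was higher in every tumour group than in naive cortex. Its level was 23.4 ± 0.995 CPM (SD, n = 3) in naive, 89.0 ± 29.7 in YAP1-MAMLD1-dR3R1, 76.7 ± 20.4 in YAP1-FAM118B and 103 ± 20.5 in YAP1-TFE3. The log2 fold changes against naive were 1.93 ± 0.27 (SE), 1.71 ± 0.27 and 2.13 ± 0.27, with edgeR adjusted p of 1.9e-04, 0.00107 and 7.54e-05. Between the fusions Yap1 did not pass (edgeR adjusted p of 0.555, 0.549 and 0.201). Fam118b (chromosome 9, 35216965 to 35267875) rose from 16.8 ± 2.81 CPM in naive to 45.1 ± 13.9 in YAP1-FAM118B tumours (edgeR adjusted p = 0.0028). It also rose to 51.2 ± 13.3 CPM in YAP1-TFE3 tumours (edgeR adjusted p = 3.84e-04), and these levels differed from each other by 0.18 ± 0.26 on the log2 scale (edgeR adjusted p = 0.573). In YAP1-MAMLD1-dR3R1 tumours Fam118b was at 18.7 ± 3.01 CPM. Tfe3 (chromosome X, 7762530 to 7775202) was highest in YAP1-TFE3 tumours at 126 ± 25.6 CPM, against 39.7 ± 4.67 in naive, 55.1 ± 9.32 in YAP1-FAM118B and 85.8 ± 9.40 in YAP1-MAMLD1-dR3R1. Its excess over YAP1-FAM118B was 1.19 ± 0.18 on the log2 scale (edgeR adjusted p = 5.72e-04). The excess over YAP1-MAMLD1-dR3R1, 0.55 ± 0.18, had an edgeR adjusted p of 0.0336, and the call ended when any 1 of the 6 libraries of these groups was left out (highest edgeR adjusted p 0.361). Mamld1 (chromosome X, 71050036 to 71156056) was at 28.2 ± 16.6 CPM in tumours carrying its own fusion against 25.8 ± 1.78 in naive (edgeR adjusted p = 0.829). It fell to 9.55 ± 5.45 CPM in YAP1-TFE3 tumours (edgeR adjusted p = 0.0255, or 0.0578 without naive replicate 2). Whether reads from a viral transcript were counted on the mouse gene depends on how closely their sequences match, which was not analysed here.

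**Figure D1:**
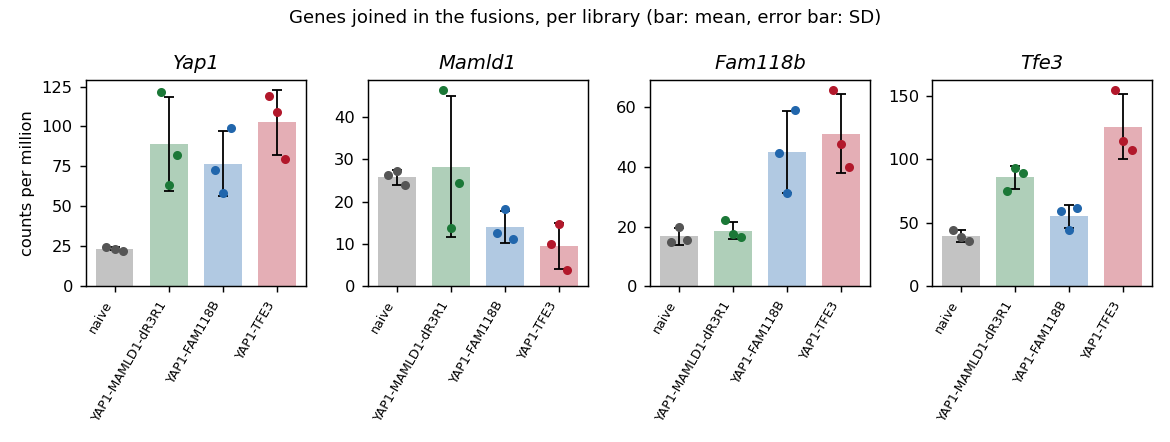
CPM (counts scaled to library size, vertical axis) of Yap1, Mamld1, Fam118b and Tfe3 in each library (points), with the mean of 3 libraries per group (bars) and the SD (error bars). Yap1 was at 23.4 CPM in naive cortex and between 76.7 and 103 CPM in the tumour groups.

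Libraries of a group resembled each other, with some overlap between tumour groups. Across the 16364 genes tested, the correlation of log2 CPM was 0.971 to 0.985 between naive libraries, 0.905 to 0.955 within YAP1-MAMLD1-dR3R1, 0.933 to 0.974 within YAP1-FAM118B and 0.911 to 0.940 within YAP1-TFE3. Between naive and YAP1-FAM118B it was 0.812 to 0.909, higher than for YAP1-MAMLD1-dR3R1 (0.617 to 0.763) or YAP1-TFE3 (0.586 to 0.737). Between fusions it was 0.793 to 0.922 for YAP1-MAMLD1-dR3R1 and YAP1-FAM118B, 0.805 to 0.865 for YAP1-MAMLD1-dR3R1 and YAP1-TFE3 and 0.727 to 0.842 for YAP1-FAM118B and YAP1-TFE3. These are correlations across genes, which are not independent replicates, and no p-value was computed. The first principal component held 57.7% of the variance and the second 19.7%.

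**Figure D2:**
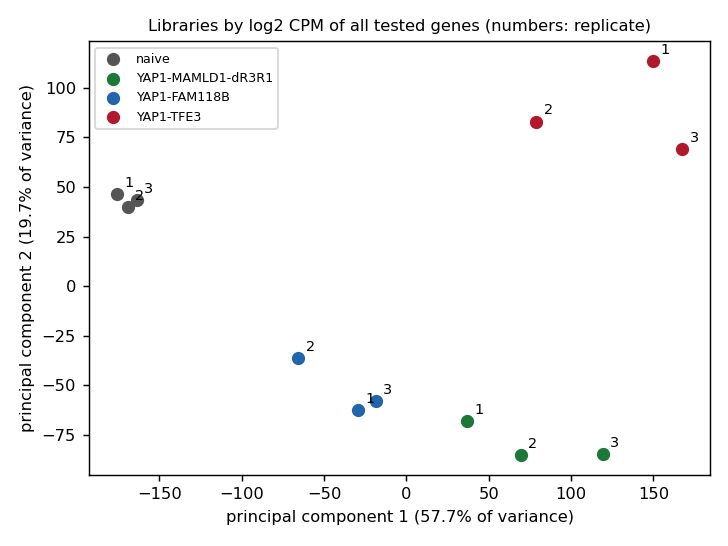
Scores of the 12 libraries on the first principal component (57.7% of the variance, horizontal axis) and the second (19.7%, vertical axis) of log2 CPM over 16364 genes, with colours for the groups. Each point is a library.

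Tumours of all 3 fusions shared a large set of changes from naive cortex. The genes that rose most in every fusion included Clec7a, a receptor for fungal glucans, Cst7, a cathepsin inhibitor of activated microglia, Arg1, the arginase of macrophages, and Mmp12, the macrophage elastase. Cxcl13 and Cxcl10, attractants of lymphocytes, and Ccl2, an attractant of monocytes, rose with them. Cxcl13 went from 0.327 CPM in naive to 1330, 166 and 441 CPM in YAP1-MAMLD1-dR3R1, YAP1-FAM118B and YAP1-TFE3 tumours. Ankrd1, a classic YAP target, rose by 8.69 ± 0.87, 9.44 ± 0.89 and 11.18 ± 0.94 on the log2 scale in the same order, and the transcription factor Runx3 by 8.93 ± 0.83, 8.22 ± 0.82 and 9.02 ± 0.83. Clec7a had only 1 count over the naive group, and its CPM ratio in YAP1-FAM118B, the smallest of its ratios, was 1565 with a 95% counting interval of 280.4 to 61838. The genes that fell most in every fusion included Irs4, an insulin receptor substrate of the hypothalamus, and Ngb, the oxygen-binding neuroglobin, with log2 fold changes of −3.87 ± 0.63, −2.63 ± 0.60 and −5.23 ± 0.69. Pmch, the precursor of melanin-concentrating hormone, fell from 62.5 CPM to 3.51, 0.777 and 3.61 CPM, but the naive libraries themselves differed, with 11.99, 28.6 and 147 CPM in replicates 1, 2 and 3. Irs4 and Pmch are genes of the hypothalamus. Their decrease, and that of other shared genes, can depend on which regions the naive samples held. In the edgeR test 9, 8 and 9 of 10 hypothalamus and midbrain genes were lower, in the order of the fusions above. This list, written after these values were seen, holds Irs4 and Pmch. Of 8 cortex neuron genes, also listed afterwards, 6, 0 and 5 were lower.

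In all, 4039 genes changed in the same direction in every fusion (edgeR quasi-likelihood test, adjusted p under 0.05 in each), 3046 higher and 993 lower. Independent lists of these sizes would share 485 higher and 119 lower genes. In 20 simulations with every group, naive included, drawn from the naive means, no gene was shared. With no gene changed the simulated lists are nearly empty, so this is no chance level for lists of the real sizes. The fold changes against naive correlated across genes at 0.845 for YAP1-MAMLD1-dR3R1 and YAP1-FAM118B, 0.804 for YAP1-MAMLD1-dR3R1 and YAP1-TFE3, and 0.696 for YAP1-FAM118B and YAP1-TFE3. Simulated unchanged groups gave 0.505, 0.501 and 0.500. The covariances were 3.32, 4.93 and 3.06 against simulated values of 0.136, 0.134 and 0.134. The 3 naive libraries could not be split into parts of at least 2 libraries, so part of the excess may come from the shared controls. The shared count was 1392 when each change was tested against 2-fold (glmTreat), and 2394 with a log2 fold change of at least 1 in each fusion.

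**Figure D3:**
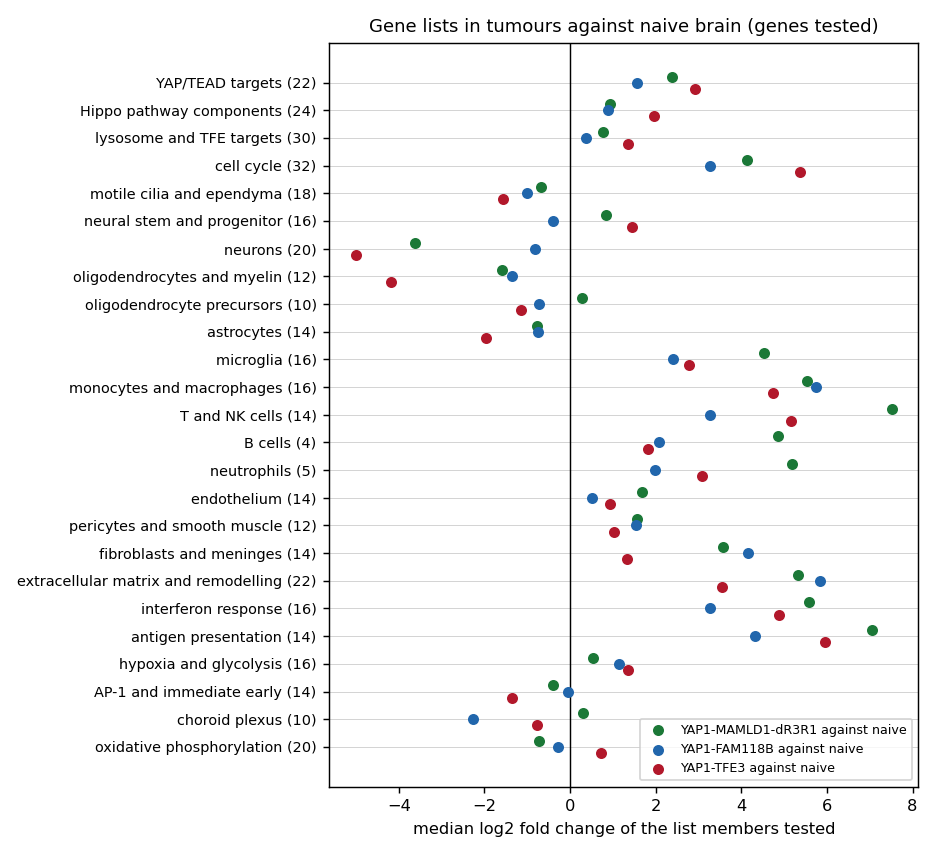
Median log2 fold change of the tested members of each gene list against naive, a marker per fusion. The cell cycle, extracellular matrix, microglia and antigen presentation lists lie above 0 in each fusion, and the neuron and myelin lists below 0.

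YAP1-MAMLD1-dR3R1 tumours carried raised proliferation, matrix and immune genes and lowered neuronal and respiratory genes compared with naive cortex. Of 32 cell cycle genes 30 rose, including Top2a, the topoisomerase of dividing cells, by 5.66 ± 0.31 on the log2 scale, and the spindle checkpoint kinase Bub1 by 6.28 ± 0.33, while Ccne1, cyclin E1, fell by 0.99 ± 0.23. All 22 genes of extracellular matrix and remodelling rose, with the collagen Col5a2 going from 3.97 to 1530 CPM. Among 22 YAP/TEAD targets 16 rose, such as the receptor kinase Axl by 3.99 ± 0.30 and Amotl2, an angiomotin that binds YAP, by 3.94 ± 0.30. Every one of 16 microglia genes rose, with C1qa, a complement subunit, going from 36.7 to 2676 CPM. So did all 14 antigen presentation genes, with B2m, the light chain of class I molecules, going from 44.7 to 2946 CPM, and all 16 interferon response genes, with Bst2, which tethers virus particles, rising by 6.04 ± 0.43. In the other direction, 18 of 20 oxidative phosphorylation genes fell, such as Ndufs1 of complex I at −1.09 ± 0.11. Of 20 neuron genes 17 fell, for instance the dendritic protein gene Map2 at −1.96 ± 0.34.

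Counts adjusted over the list alone were the same for the cell cycle, matrix, microglia, antigen presentation and interferon lists. For YAP/TEAD targets they were 16 higher and 2 lower against 16 and 1 over all genes, for oxidative phosphorylation 19 lower and for neurons 19 lower. Camera adjusted p was 4.05e-34 for the cell cycle list (adjusted p = 0.258 with an estimated correlation). For YAP/TEAD targets it was 9.32e-05, for matrix 2.9e-11, for microglia 7.4e-10, for antigen presentation 8.17e-08 and for oxidative phosphorylation 1.01e-04, and each had an adjusted p = 0.459 with an estimated correlation. The interferon list had 2.79e-06 (adjusted p = 0.540 with an estimated correlation) and the neuron list 4.34e-04 (adjusted p = 0.598 with an estimated correlation). In total 10339 of 16364 genes changed (edgeR quasi-likelihood test, Benjamini-Hochberg), 5627 higher and 4712 lower, and 7219 of them by at least 2-fold; 5053 passed a test against 2-fold. Of the neuron genes 7 were called without YAP1-MAMLD1-dR3R1 replicate 2, 8 without replicate 3, 9 without naive replicate 1 and 11 without naive replicate 2. In simulated libraries of this comparison, with far fewer genes changed than in the data, the test recovered 19 of 100 genes changed 2-fold and 83 of 100 changed 4-fold. Fewer changed genes make the adjusted cutoff stricter, so these shares do not carry over to the data.

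YAP1-FAM118B tumours differed least from naive cortex by the number of genes called, and most of the called genes were higher. Proliferation and matrix genes rose again: 29 of 32 cell cycle genes, with Bub1 by 5.98 ± 0.32, and all 22 matrix genes, with Col5a2 at 1748 CPM. Bone-resorbing enzymes were among the largest increases, chiefly in replicates 1 and 3. Mmp13, a collagenase, stood at 690 CPM with only 2 counts over the naive group, a ratio of 23960 with a counting interval of 6632.5 to 197853, and Acp5, the tartrate-resistant acid phosphatase of osteoclasts, went from 0.442 to 1608 CPM. YAP1-FAM118B replicate 2 held 22.8 CPM of Acp5, against 2056 and 2745 in replicates 1 and 3. Foxd3, a transcription factor of neural crest, was at least 544-fold higher than naive, against a floor of 3 counts over the group, and at least 860-fold higher in YAP1-MAMLD1-dR3R1. Among 14 fibroblast and meninges genes 9 rose, such as the collagen Col1a1, which rose by 8.13 ± 1.04 to 3086 CPM, with 660.4 CPM in replicate 2 against 3626 and 4971 in replicates 1 and 3. The mean log2 CPM of this list was 5.20 in replicate 2 and 7.89 and 7.94 in the others, the libraries that also held the bone-resorbing enzymes, and 15 of 22 YAP/TEAD targets rose, with Amotl2 by 3.51 ± 0.29. Of 16 hypoxia and glycolysis genes 9 rose, including hexokinase 2 (Hk2) by 3.92 ± 0.17 and carbonic anhydrase 9 (Car9) by 4.61 ± 0.56. Of 16 microglia genes 12 rose, with C1qa at 573 CPM, as did 15 of 16 monocyte and macrophage genes and all 14 antigen presentation genes. Of 20 neuron genes, with a median log2 fold change of −0.82, only Map2 passed, at −1.02 ± 0.33 (edgeR adjusted p = 0.0442).

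Adjusted over the list alone, the counts were 30 for cell cycle, 22 for matrix, 10 for fibroblasts, 15 for YAP/TEAD targets, 13 for hypoxia, 12 for microglia, 16 for monocytes and macrophages, 14 for antigen presentation and none for neurons. Camera adjusted p was 2.32e-52 for cell cycle (adjusted p = 0.0541 with an estimated correlation), 8.24e-25 for matrix (0.132 as the adjusted p with an estimated correlation) and 1.39e-07 for YAP/TEAD targets (0.255 as the adjusted p with an estimated correlation). It was 1.52e-04 for fibroblasts, 1.18e-05 for hypoxia and 1.48e-08 for antigen presentation, each with an adjusted p = 0.381 with an estimated correlation. For microglia it was 4e-07 (adjusted p = 0.414 with an estimated correlation) and for monocytes and macrophages 1.15e-09 (adjusted p = 0.251 with an estimated correlation). The edgeR test called 4861 genes, 3479 higher and 1382 lower, and 2898 of them changed at least 2-fold; 1639 passed a test against 2-fold. DESeq2 moved the split to 3804 higher and 2842 lower. Leaving out YAP1-FAM118B replicate 1 gave 3106 genes, 405 of them lower, leaving out replicate 3 gave 2979 with 356 lower, and leaving out naive replicate 1 gave 415 lower. The call of Map2 ended without naive replicate 1 (edgeR adjusted p = 0.143), 2 (0.0951) or 3 (0.0751) and without YAP1-FAM118B replicate 1 (0.137) or 3 (0.155). In simulated libraries, with far fewer genes changed and so a stricter cutoff, the test recovered 19 of 100 genes changed 2-fold and 76 of 100 changed 4-fold.

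YAP1-TFE3 tumours moved furthest from naive cortex. Lysosomal genes and other targets of the TFE family rose in 23 of 30 cases and fell in 4, with Gpnmb, a melanosome and lysosome glycoprotein, going from 7.06 to 8104 CPM and the lysosomal enzyme gene Naglu rising by 4.77 ± 0.23. In contrast to YAP1-MAMLD1-dR3R1 tumours, 15 of 20 oxidative phosphorylation genes rose and 1 fell, for example Cox5a of cytochrome oxidase from 143 to 530 CPM. Of 24 Hippo pathway components 20 rose, such as the kinase Lats2 by 3.59 ± 0.30 and the DNA-binding partner of YAP, Tead1, by 4.12 ± 0.34; 16 of 22 YAP/TEAD targets rose and 4 fell. Cell cycle genes rose in 30 of 32 cases, among them the spindle factor Tpx2 by 5.41 ± 0.22. Hypoxia and glycolysis genes rose in 11 of 16 cases, with Hk2 by 5.88 ± 0.18 and the angiogenic factor Vegfa by 3.51 ± 0.34. Smooth muscle actin (Acta2) went from 14.4 to 3767 CPM. Slc34a2, a phosphate transporter of lung epithelia, had only 2 counts over the naive group. Its CPM ratio was 6256 with a counting interval of 1732 to 51667, carried mostly by replicate 3. The level of Slc34a2 was 469 CPM in that replicate, against 9.98 and 50.2 in replicates 1 and 2. Matrix genes rose in 19 of 22 cases and all 14 antigen presentation genes rose. Genes of the normal brain fell: 19 of 20 neuron genes, all 12 myelin genes and 10 of 14 astrocyte genes, although Aldh1l1, a folate enzyme of astrocytes, rose by 3.66 ± 0.37. The mean log2 CPM of the neuron list was 0.905, 5.11 and 1.17 in YAP1-TFE3 replicates 1, 2 and 3, so replicate 2 stood apart.

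Counts adjusted over the list alone were identical for these lists except YAP/TEAD targets, with 17 higher and 4 lower. Camera adjusted p was 7.7e-05 for lysosome, matrix and neurons, 1.96e-04 for YAP/TEAD targets and Hippo components, 0.00145 for hypoxia, 2.77e-04 for antigen presentation and 3.89e-05 for myelin, and each had an adjusted p = 0.603 with an estimated correlation. For cell cycle it was 2.26e-39 (adjusted p = 0.141 with an estimated correlation). The oxidative phosphorylation list had 0.0322 (adjusted p = 0.619 with an estimated correlation), and that call ended without naive replicate 1 (0.0662) or YAP1-TFE3 replicate 2 (0.0610) or 3 (0.117). The astrocyte list had 0.0339 (adjusted p = 0.619 with an estimated correlation) and passed neither without YAP1-TFE3 replicate 1 (0.0640) nor without replicate 3 (0.0833). The edgeR test called 11547 genes, 6641 higher and 4906 lower, with 8490 changed at least 2-fold; 6538 passed a test against 2-fold. The median log2 fold change of all genes was 0.23, and it shifted by −0.19 with library size alone, by −0.15 with RLE factors and with DESeq2 and by −0.12 with upper-quartile factors. With library size alone 11 oxidative phosphorylation genes were higher. In simulated libraries, with far fewer genes changed and so a stricter cutoff, the test recovered 22 of 100 genes changed 2-fold and 79 of 100 changed 4-fold.

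Compared with YAP1-MAMLD1-dR3R1 tumours, YAP1-FAM118B tumours held lower microglia, antigen presentation and proliferation genes and higher respiratory genes. All 16 microglia genes were lower, including C1qa at a log2 fold change of −2.22 ± 0.39, and 9 of 14 antigen presentation genes, such as B2m at −2.36 ± 0.38. Only 3 of 16 monocyte and macrophage genes (camera adjusted p = 0.252) and 1 of 5 neutrophil genes were lower. Of 14 T and NK cell genes 2 were called lower over all genes and 11 over the list alone, with a median log2 fold change of −3.80. That list passed camera as lower (adjusted p = 0.00288, or 0.684 with an estimated correlation). Of 32 cell cycle genes 17 were lower, for instance the replication helicase subunit Mcm3 at −1.40 ± 0.22. Higher genes included the collagenase Mmp13 at 690 against 0.696 CPM, although at 7.64 CPM in YAP1-FAM118B replicate 2, Lep, the hormone leptin, by 6.56 ± 1.23, and Oscar, a collagen receptor of osteoclasts, by 6.56 ± 1.35, with 28.2, 1.26 and 52.1 CPM in YAP1-FAM118B replicates 1, 2 and 3. The growth factor gene Gdf6, the retinoic acid binding protein gene Crabp1 and Dio3, which inactivates thyroid hormone, were lower, at −6.19 ± 0.99, −5.71 ± 0.86 and −5.53 ± 0.69. Oxidative phosphorylation genes were higher in 12 of 20 cases, with Ndufs1 by 0.68 ± 0.11. Neuron genes had a median log2 fold change of 2.73, with 2 of 20 called, and the lysosome list was divided, with 8 of 30 higher, such as the proton pump subunit Atp6v1b2 by 1.33 ± 0.15, and 10 lower, such as the protease Ctsd at −1.77 ± 0.23. No gene of the matrix list was called by the edgeR test, at unadjusted p under 0.05 or by DESeq2.

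Adjusted over the list alone, 16 microglia, 12 antigen presentation and 21 cell cycle genes were lower, 16 oxidative phosphorylation and 2 neuron genes higher, and lysosome genes numbered 9 higher and 11 lower. Camera adjusted p was 3.1e-11 for microglia, 3.5e-07 for antigen presentation, 7.66e-07 for cell cycle and 2.59e-04 for oxidative phosphorylation, each with an adjusted p = 0.623 with an estimated correlation. For neurons it was 4.27e-06 (adjusted p = 0.684 with an estimated correlation). The edgeR test called 4293 genes, 2085 higher and 2208 lower, with 2447 changed at least 2-fold; 8 passed a test against 2-fold. The near-even split turned in other fits, for example to 1040 higher and 626 lower without YAP1-MAMLD1-dR3R1 replicate 2. With the normal brain covariate 2 genes passed (2663 at unadjusted p under 0.05), with the immune cell covariate 0 (2706; DESeq2 was not run with covariates) and in tumours alone with neither, a fit added after the data were seen, 2537. This comparison rested on few libraries: the count was 1666 and 1798 without YAP1-MAMLD1-dR3R1 replicates 2 and 3, and 1753 and 1932 without YAP1-FAM118B replicates 1 and 2. Without these libraries in the same order the lower cell cycle genes numbered 4, 4, 4 and 7 (11 without YAP1-FAM118B replicate 3), the lower microglia genes 8 without each of the first 3 of them, and the higher oxidative phosphorylation genes 3 without YAP1-FAM118B replicate 1 and 6 without replicate 2. Lower lysosome genes numbered 5, 6, 6 and 5 in that order, and higher lysosome genes 5 without YAP1-FAM118B replicate 1. In simulated libraries, with far fewer genes changed and so a stricter cutoff, the test recovered 24 of 100 genes changed 2-fold and 77 of 100 changed 4-fold.

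YAP1-TFE3 tumours, against YAP1-MAMLD1-dR3R1 tumours, held higher lysosome, respiratory and proliferation genes and lower microglia, matrix and oligodendrocyte genes. Lysosome and TFE target genes were higher in 21 of 30 cases, among them Gpnmb at 8104 against 154 CPM, the galactosidase Gla by 2.56 ± 0.21 and the lysosomal channel gene Mcoln1 by 1.44 ± 0.14. Of 20 oxidative phosphorylation genes 19 were higher, with Cox5a by 2.63 ± 0.11, and 24 of 32 cell cycle genes, with the ribonucleotide reductase subunit Rrm2 by 3.81 ± 0.31. Among the genes with the largest increases were Tph1, the serotonin-synthesis enzyme of gut and pineal, from 0.305 to 397 CPM, Nppb, a natriuretic peptide of heart, at least 1103-fold against a floor of 3 counts over the group, and Trim63, a ubiquitin ligase of muscle, with 3 counts over the lower group and a ratio of 3413.5 and a counting interval of 1168 to 16555. Osr1, a transcription factor of mesoderm, was lower, at −9.46 ± 0.70 on the log2 scale. Microglia genes were lower in 14 of 16 cases, such as C1qa at −2.42 ± 0.39, and 10 of 22 matrix genes, for example Col8a1, a collagen of vessel walls, at −6.15 ± 0.69. Myelin genes were lower in 10 of 12 cases and oligodendrocyte precursor genes in 6 of 10, including their regulator Sox10 at −3.28 ± 0.49. Hypoxia and glycolysis genes were higher in 9 of 16 cases, with Vegfa by 2.85 ± 0.33.

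Adjusted over the list alone, 23 lysosome, 19 oxidative phosphorylation, 27 cell cycle and 10 hypoxia genes were higher, and 14 microglia, 10 matrix, 11 myelin and 8 precursor genes lower. Camera adjusted p was 1.62e-06 for lysosome and 2.96e-11 for cell cycle, each with an adjusted p = 0.466 with an estimated correlation, and 8.02e-19 for oxidative phosphorylation (adjusted p = 0.198 with an estimated correlation). For hypoxia it was 2.01e-04, for microglia 1.51e-06 and for myelin 1.12e-04, each with an adjusted p = 0.682 with an estimated correlation. The matrix and precursor lists had 0.0011 and 0.00128, each with an adjusted p = 0.726 with an estimated correlation. Antigen presentation genes ranked lower as a list (camera adjusted p = 0.0396; adjusted p = 0.783 with an estimated correlation) although edgeR called none of 14, 1 had an unadjusted p under 0.05 and DESeq2 called 3. That list did not pass without YAP1-MAMLD1-dR3R1 replicate 2 (0.164) or 3 (0.156) or YAP1-TFE3 replicate 1 (0.137) or 2 (0.273). The edgeR test called 6456 genes, 3695 higher and 2761 lower, with 3952 changed at least 2-fold; 1561 passed a test against 2-fold. The direction of this split is not settled: library size alone gave 2803 higher and 3866 lower, and upper-quartile factors 3031 and 3599, with the median of all genes shifted by −0.19 and −0.14. It also turned without YAP1-MAMLD1-dR3R1 replicate 2 (2364 and 2650) or 3 (2458 and 3228), without YAP1-TFE3 replicate 1 (2461 and 2492), 2 (2700 and 3967) or 3 (2916 and 3552), with no filter (2787 and 3441), with CPM of at least 1 in 3 libraries (2904 and 3651) and with DESeq2 (3849 and 3958). The lysosome, cell cycle and oxidative phosphorylation lists kept a median above 0 under each scaling. In simulated libraries, with far fewer genes changed and so a stricter cutoff, the test recovered 16 of 100 genes changed 2-fold and 78 of 100 changed 4-fold.

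Between YAP1-TFE3 and YAP1-FAM118B tumours, lysosome and proliferation genes were higher in the former and neuronal and fibroblast genes in the latter. Gpnmb stood at 8104 against 16.9 CPM, the melanosome antigen gene Mlana was at least 843-fold higher against a floor of 3 counts over the group, at 1.78, 30.1 and 75.8 CPM in the YAP1-TFE3 replicates, and Trpm1, a channel named for its loss in melanoma, rose by 10.06 ± 1.01. Lysosome and TFE target genes were higher in 19 of 30 cases, with Naglu by 2.34 ± 0.21. Cell cycle genes were higher in 29 of 32, with Rrm2 by 4.71 ± 0.32, oxidative phosphorylation genes in 17 of 20, with Cox5a by 2.12 ± 0.11, and Hippo components in 14 of 24, with Lats2 by 2.13 ± 0.28 and the scaffold gene Wwc1 by 2.29 ± 0.23. Ctsk, the collagen-digesting cathepsin of osteoclasts, was at 4.86 against 1953 CPM, the latter from 2138, 22.3 and 3699 CPM in replicates 1, 2 and 3, and Lep was lower, at −9.33 ± 1.47. Of 20 neuron genes 18 were lower, such as Map2 at −2.22 ± 0.35, as were 10 of 12 myelin genes. Fibroblast genes were lower in 10 of 14 cases, with Col1a1 at −6.47 ± 0.96. Immediate early genes, switched on within minutes of a stimulus, were lower in 7 of 14, such as Fos at −1.89 ± 0.33. Of 16 microglia genes edgeR called 0 and DESeq2 called 1, and 1 had an unadjusted p under 0.05 in edgeR.

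Adjusted over the list alone, 20 lysosome, 30 cell cycle, 19 oxidative phosphorylation and 14 Hippo genes were higher, and 19 neuron, 10 myelin, 10 fibroblast and 7 immediate early genes lower. Camera adjusted p was 1.6e-05 for lysosome, 3.87e-19 for cell cycle and 1.66e-07 for oxidative phosphorylation, each with an adjusted p = 0.531 with an estimated correlation. For Hippo components and immediate early genes it was 0.00922, and for myelin 1.45e-04, each with an adjusted p = 0.769 with an estimated correlation. Neurons had 8.96e-06 and fibroblasts 0.0112, each with an adjusted p = 0.796 with an estimated correlation, and the fibroblast list did not pass without YAP1-TFE3 replicate 2 (0.0613) or 3 (0.0877). Without YAP1-TFE3 replicate 2, 11 immediate early genes were lower, and 11 neuron genes were lower without YAP1-FAM118B replicate 2 or YAP1-TFE3 replicate 1 or 3. The edgeR test called 8460 genes, 4582 higher and 3878 lower, with 5434 changed at least 2-fold; 3092 passed a test against 2-fold. The direction of this split is not settled: library size alone gave 3386 higher and 4812 lower, with the median of all genes shifted by −0.21, and leaving out YAP1-TFE3 replicates 1, 2 and 3 in turn gave 2792 and 4141, 2941 and 4833, and 3063 and 4786. It also turned with RLE (4127 and 4204) and upper-quartile factors (4088 and 4239), with no filter (3343 and 4605), with CPM of at least 1 in 3 libraries (3136 and 4957), with DESeq2 (4584 and 4702) and when tested against 2-fold (1337 and 1755). In simulated libraries, with far fewer genes changed and so a stricter cutoff, the test recovered 17 of 100 genes changed 2-fold and 65 of 100 changed 4-fold.

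Each fusion also had genes called in the same direction against both others by the edgeR test. YAP1-TFE3 tumours had the most: 2965 higher, including the apoptosis inhibitor Birc7 at 170 CPM against 0.110 in YAP1-MAMLD1-dR3R1, and 1591 lower, including Osr1 at 0.0598 CPM against 47.1 and 32.4. Of these, 2641 and 1263 had moved the same way from naive. The direction of this split is not settled: it turned with library size alone (2154 higher and 2313 lower), with CPM of at least 1 in 3 libraries (2109 and 2334) and without YAP1-MAMLD1-dR3R1 replicate 3 (1938 and 2297) or YAP1-TFE3 replicate 2 (1998 and 2912) or 3 (2130 and 2243). YAP1-MAMLD1-dR3R1 tumours had 751 higher genes, such as Gdf6 at 78.5 CPM against 1.06 and 0.603, and 602 lower, with 697 and 548 also called against naive. YAP1-FAM118B tumours had 1340 higher genes, such as Oscar at 27.2 CPM (1.26 in replicate 2) against 0.277 and 0.269, and 1101 lower, but only 61 and 19 of them had also moved the same way from naive. The total for YAP1-MAMLD1-dR3R1 was 1353, and 561 and 624 without its replicates 2 and 3 and 579 and 710 without YAP1-FAM118B replicates 1 and 2. The total for YAP1-FAM118B was 2441, and 981, 1067, 1019 and 1113 without the same libraries. Its split was 1251 higher and 1255 lower with upper-quartile factors and 1273 and 677 with no filter.

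Other lists moved less evenly. Against naive, T and NK cell genes rose in 12 of 14 cases in YAP1-MAMLD1-dR3R1 (camera adjusted p = 0.0292; adjusted p = 0.598 with an estimated correlation), in 2 in YAP1-FAM118B and in 10 in YAP1-TFE3, where 5 and 6 passed without naive replicates 1 and 2 and 3 without YAP1-TFE3 replicate 3. Endothelial genes rose in 11, 2 and 7 of 14 cases, pericyte and smooth muscle genes in 8, 6 and 4 of 12 (5 in YAP1-MAMLD1-dR3R1 without naive replicate 1), and neutrophil genes in 3 of 5 in each fusion. B cell genes rose in 3 and 1 of 4 cases in YAP1-MAMLD1-dR3R1 and YAP1-TFE3. In YAP1-FAM118B edgeR called no B cell gene, with 1 at unadjusted p under 0.05 and 1 by DESeq2. Neural stem genes rose in 6, 5 and 10 of 16 cases, including Nes, the nestin filament, by 4.02 ± 0.18 in YAP1-MAMLD1-dR3R1. Of 18 genes of motile cilia 7 were lower and 2 higher in YAP1-TFE3, where their regulator Foxj1 rose by 4.04 ± 0.57. The list did not pass camera there (adjusted p = 0.122). It passed as lower in YAP1-FAM118B (camera adjusted p = 0.00998, or 0.509 with an estimated correlation). In that fusion 2 members were called lower over all genes and 0 over the list alone. Choroid plexus genes rose in 2, 1 and 1 of 10 cases. Adjusted over the list alone, the counts in the order of the fusions were 12, 2 and 10 for T and NK cells, 11, 1 and 7 for endothelium, 8, 6 and 3 for pericytes, 3 each for neutrophils, 3, 0 and 1 for B cells, 5, 5 and 10 for neural stem genes, 7 lower cilia genes in YAP1-TFE3 and 1, 1 and 0 for choroid plexus. Of the blood list only Alas2, an enzyme of haem synthesis, was tested, and edgeR, its unadjusted p under 0.05 and DESeq2 called it in 0 comparisons. The camera direction was opposite in sign to the median for neural stem genes in YAP1-FAM118B (median −0.39) and choroid plexus in YAP1-MAMLD1-dR3R1 (0.31) against naive. The same held for astrocytes (0.19), pericytes (−0.04) and blood (0.40) between YAP1-FAM118B and YAP1-MAMLD1-dR3R1, for choroid plexus between YAP1-TFE3 and YAP1-FAM118B (0.94) and for blood between YAP1-TFE3 and naive (0.85), and none of these passed camera.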

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

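The tests of cell and tissue shares, of spread and of bone, the osteoclast list and the counts of other splits were chosen after the result was seen; the edgeR and camera tests and the count of lysosome genes under scaling by library size were planned. Fusions that share a control can move a gene in opposite directions from it. Between YAP1-MAMLD1-dR3R1 and YAP1-FAM118B, 5 genes did so with the fusions also differing from each other in the edgeR test: Emilin3, a matrix glycoprotein (−3.02 ± 1.14 and 2.70 ± 0.82), Padi2, which citrullinates proteins (0.81 ± 0.32 and −0.96 ± 0.33), Pla2g16, a phospholipase (0.91 ± 0.23 and −0.67 ± 0.23), Sfrp5, a WNT antagonist (2.43 ± 0.91 and −3.12 ± 0.98), and St3gal6, a sialyltransferase (0.70 ± 0.17 and −0.53 ± 0.17). All but Sfrp5 are named after their values were seen. Between YAP1-MAMLD1-dR3R1 and YAP1-TFE3 there were 408 such genes, 314 higher in YAP1-TFE3 and 94 higher in YAP1-MAMLD1-dR3R1, including Osr1 and Dio3. Between YAP1-FAM118B and YAP1-TFE3 there were 128, of which 94 were higher in YAP1-TFE3, including Upk3bl, a urothelial plaque gene. Oxidative phosphorylation genes moved apart as a list, with a median log2 fold change of 1.48 in YAP1-TFE3 against YAP1-MAMLD1-dR3R1 and of 1.00 against YAP1-FAM118B. Both passed camera (adjusted p = 8.02e-19 and 1.66e-07) but not with an estimated correlation (adjusted p = 0.198 and 0.531).

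Lysosome and TFE target genes were higher in YAP1-TFE3 than in the other fusions, and 2 technical explanations were tested. More microglia and macrophages in those samples would raise their marker lists at least as much, but the lysosome median lay above the median of both immune lists by 1.09 against YAP1-FAM118B (0.96 and −0.13; permutation p = 6.4e-04 over genes, two-sided). Against YAP1-MAMLD1-dR3R1 it lay above by 2.70 (permutation p = 1e-05, the smallest these permutations give). The permutations treat genes as independent although genes of a list can move together, so their p-values do not measure the spread between samples. With an estimated correlation the lysosome list itself did not pass camera (adjusted p = 0.531 against YAP1-FAM118B and 0.466 against YAP1-MAMLD1-dR3R1). TMM scaling was argued against by counts of 17 and 20 of 30 genes higher with library size alone, against YAP1-FAM118B and YAP1-MAMLD1-dR3R1. The fusion partner, which the groups name, stays open as an untested explanation.

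YAP1-FAM118B had the fewest genes changed against naive. A larger share of tissue like the naive samples was not decided. If the rest of each sample were like YAP1-MAMLD1-dR3R1, neuron genes would give that share as 0.529 and myelin genes as 0.0704, a difference of 0.459. With YAP1-TFE3 in that place they would give 0.543 and 0.329, a difference of 0.214. These shares rest on an assumed makeup of the tumour part, and no table gives its own neuron and myelin levels. Brain tissue of another makeup stays open as well. A wider spread between its libraries was not decided by the count of genes with at least a 2-fold change, called or not. They numbered 4691 against 8296 in YAP1-MAMLD1-dR3R1, a ratio of 0.565, which became 0.724 without YAP1-FAM118B replicate 2. The ratio to YAP1-TFE3 was 0.500, and 0.641 without that replicate. But correlations within YAP1-FAM118B were not lower (median 0.955, against 0.941 in YAP1-MAMLD1-dR3R1 and 0.940 in YAP1-TFE3). Over the 1000 most variable genes they were 0.862, 0.800 and 0.781. These correlations argue against a wider spread over all tested genes, though not for single genes. The groups shared an estimate of the spread in the model, which cannot show whether a group varied more than the others. The fusion partner, which the groups name, was not tested as an explanation.

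Osteoclast genes were high in YAP1-FAM118B replicates 1 and 3, where Acp5, Ctsk and the gelatinase Mmp9 were at 2056, 2138 and 2280 CPM and at 2745, 3699 and 3426 CPM, against 22.8, 22.3 and 23.3 CPM in replicate 2. An osteoclast list written after these genes were seen had 11 of 14 members at least 2-fold above replicate 2 in each library. Its median rise was 3.53 and 4.15 on the log2 scale in replicates 1 and 3. This exceeded the median of the combined microglia and macrophage lists by 3.01 and 3.82. The 2 lists differed, with medians of 0.04 and −0.07 for microglia and of 1.76 and 1.84 for monocytes and macrophages. Macrophage genes thus rose as well, though by less than the osteoclast list. More macrophages of every kind were not excluded, since F13a1, a clotting factor of macrophages, was 3.93 and 3.95 above replicate 2 on the log2 scale, more than the osteoclast median of 3.53 in replicate 1, by a bound on single genes set after these values were seen. These are differences between single libraries. Bone in those samples could not be decided either. Osteoblast and osteocyte genes summed to 0.697% and 0.677% of the osteoclast genes, but Ibsp, bone sialoprotein, was at 37.0 and 62.1 CPM in these libraries and 0.378 in replicate 2, and the condition on single bone genes was added after Ibsp was seen.

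Other splits of the libraries were counted for each comparison. The 10 splits of 6 libraries into groups of 3 cannot give a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. Against naive the real split and the highest other called 10339 and 0 genes for YAP1-MAMLD1-dR3R1 (10982 and 608 at unadjusted p under 0.05), 4861 and 1 for YAP1-FAM118B and 11547 and 0 for YAP1-TFE3 (11924 and 583). Between fusions they called 4293 and 0 for YAP1-FAM118B against YAP1-MAMLD1-dR3R1 (6909 and 1579 at unadjusted p under 0.05), 6456 and 575 for YAP1-TFE3 against YAP1-MAMLD1-dR3R1 and 8460 and 0 for YAP1-TFE3 against YAP1-FAM118B (9443 and 1341). DESeq2 was not run on the splits. For the 4039 shared genes 1 of 100 groupings of all libraries, the real one, gave as many, and the highest other gave 0. The other groupings mostly mix naive and tumour libraries, so this count shows that tumours differed from naive. It cannot decide whether the fusions shared more genes than chance gives. For genes set apart 1 of 100 groupings gave as many as the 1353 of YAP1-MAMLD1-dR3R1 (highest other 1294) and 1 of 100 as the 4556 of YAP1-TFE3 (highest other 4020). For the 2441 of YAP1-FAM118B it was 2 of 100, with 3873 as the highest other, and the makeup of that grouping was not examined.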

How the results depend on the processing

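The fit without both libraries that held Xist and Y-linked counts and the fit of tumours alone with no covariate were chosen after seeing the data; every other alternative here was planned. Tested against 2-fold (glmTreat), the changed genes numbered 5053, 1639 and 6538 for YAP1-MAMLD1-dR3R1, YAP1-FAM118B and YAP1-TFE3 against naive. They numbered 8 for YAP1-FAM118B against YAP1-MAMLD1-dR3R1, 1561 for YAP1-TFE3 against YAP1-MAMLD1-dR3R1 and 3092 for YAP1-TFE3 against YAP1-FAM118B, since this test asks for larger changes. The shared genes fell to 1392, or to 2394 with at least 2-fold in each fusion, and 3, 5 and 1100 were set apart in YAP1-MAMLD1-dR3R1, YAP1-FAM118B and YAP1-TFE3.

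In tumours alone with no covariate 2537 genes differed between YAP1-FAM118B and YAP1-MAMLD1-dR3R1, and 807 and 1420 were set apart in YAP1-MAMLD1-dR3R1 and YAP1-FAM118B. In tumours alone with a normal brain covariate, 2 genes differed between YAP1-FAM118B and YAP1-MAMLD1-dR3R1 (edgeR; 2663 at unadjusted p under 0.05) and 803 between YAP1-TFE3 and YAP1-FAM118B, and 0, 2 and 761 were set apart in YAP1-MAMLD1-dR3R1, YAP1-FAM118B and YAP1-TFE3. With an immune cell covariate the YAP1-FAM118B and YAP1-MAMLD1-dR3R1 pair gave 0 (edgeR; 2706 at unadjusted p under 0.05; DESeq2 was not run with covariates), YAP1-TFE3 against YAP1-MAMLD1-dR3R1 gave 1762, and 0, 0 and 1625 were set apart. For the first pair the median SE was 0.28 with no covariate and 0.34 and 0.38 with the brain and immune covariates, and the median absolute log2 fold change was 0.51, 0.39 and 0.47. With the brain covariate 3 genes of YAP1-TFE3 against YAP1-FAM118B changed sign and did not pass: Gad1 (0.49, edgeR adjusted p = 0.711), Jchain (−1.45, 0.871) and Cd79a (−0.20, 0.980). The cause was not tested.

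DESeq2 set 2067 genes apart in YAP1-MAMLD1-dR3R1, and fits of only the groups compared set 741 apart. Without both libraries that held Xist and Y-linked counts, 1010 genes differed between YAP1-FAM118B and YAP1-MAMLD1-dR3R1, and 360 and 613 were set apart in YAP1-MAMLD1-dR3R1 and YAP1-FAM118B. The cause was not tested. Leaving out 1 library at a time gave 2979 to 5475 genes for YAP1-FAM118B against naive and 1666 to 4676 for YAP1-FAM118B against YAP1-MAMLD1-dR3R1. It gave 561 to 1846 genes set apart in YAP1-MAMLD1-dR3R1 and 981 to 2828 in YAP1-FAM118B. Over the 1000 most variable genes the median correlation of naive and YAP1-TFE3 was −0.24.

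The replicate numbers did not pair the libraries: 4 of 18 same-numbered pairs had deviations correlated above 0.1 (range −0.11 to 0.324), and 4 of 12 libraries correlated best with their own number. With the replicate block the counts were 10186, 4717 and 11330 against naive and 4194, 6391 and 8222 between fusions, in the order above. Over all alternatives, named genes kept direction and call in 13400 cases, lost the call in 1203 (413 by leaving out 1 library), gained it in 134 and changed sign in 3. Lists did so in 1249, 111 (74 of them with an estimated correlation), 44 and 0 cases.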

Other observations

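No test was added in this part, and the lists and genes in it were chosen after their values were seen. YAP1-TFE3 tumours expressed genes of pigment cells: of 11 tested genes in a melanocyte list 8 were higher and 2 lower than naive in the edgeR test. The melanosome gene Pmel was at 2268, 290 and 380.0 CPM in the replicates, and the transporter gene Oca2 at 366, 339 and 202 CPM. The pigment enzyme genes Tyrp1 and Dct were at 323 and 291 CPM in replicate 2 only, against 5.31 and 2.46 in replicate 1 and 1.58 and 1.02 in replicate 3. Mitf, the regulator of melanocytes, was at 12.2, 4.83 and 10.7 CPM. Its mean of 9.24 CPM stood against 8.72 in naive, 22.4 in YAP1-MAMLD1-dR3R1 and 17.6 in YAP1-FAM118B. Sox10 and Kit, also in the melanocyte list, were at 19.6 and 13.2 CPM, against 46.5 and 49.7 in naive.

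The naive libraries differed in genes that mark brain regions. Hcrt, the hypothalamic orexin precursor, was at 0.164, 1.55 and 43.0 CPM in replicates 1, 2 and 3, Tcf7l2, a thalamic factor, at 4.19, 6.62 and 78.2 CPM, and Slc6a3, the dopamine transporter, at 73.4, 0.545 and 46.7 CPM. The cortical factor Tbr1 was at 134, 79.3 and 27.2 CPM.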
